A study of Homo sapiens with 5 samples.

How the data were processed

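BJAB cells, an established human B-lymphoma line, had been transfected by electroporation with a TBL1XR1 siRNA or with plasmids for GFP-tagged TBL1XR1 (3 µg per transfection), and 300 ng of total RNA per sample had been labelled with Cy3, per the labels' protocols. Each of 5 samples was hybridised to its own array, and the 5 groups were read from the sample titles: control, TBL1XR1 siRNA, and wild-type, L282P or H348Q TBL1XR1 plasmid. What the control cells received and the time of RNA collection are not given in the sources used here.

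The deposited scanner files hold intensity values per spot. Per the file headers, Agilent Feature Extraction 11.5.1.1 read each array in 1 colour on a design annotated to hg19, subtracted background and detrended the processed signal, and set no scale between arrays. Median pixel intensity of spot and local background, per the file headers, stand beside it without correction. The authors' deposited table of the series holds linear ratio values for 30285 probes. Set against the scanner files, its log2 differences between any 2 arrays equalled those of the processed signal up to 1 constant per pair (100.0% of probes within 0.01 log2), so each column differed from the processed signal only by 1 factor per array, which the sources used here do not name, and each probe by a baseline. That baseline stays unknown: only 5.65% of probes had a median of 1 over the 5 arrays and 3.45% a mean log2 of 0. The column medians in the authors' deposited table were 0.931 (control), 0.930 (siRNA), 0.946 (wild type), 1.04 (L282P) and 0.980 (H348Q).

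Control spots and spots marked as outliers by the scanner software were left out (318 to 459 of 43118 spots per array). The main values were log2 of the processed signal minus the array's 75th percentile over the remaining spots, where that percentile lay between 1101 and 1317 units of intensity. Copies of a probe were averaged, which concerned 999 probes with 10 copies each. Their median SD within an array was 0.0494 to 0.0585 log2 for bright probes, and SEs printed beside ratios come from this spread at the probe's level, so they cover spot noise alone and not the variation between cultures. The number of arrays limits all precision here. A gene was represented by its probe with the highest mean over the 5 arrays, and by another rule in an alternative. Probes were named through the transcript accession in the files and a RefSeq table of assembly GRCh38.p14: 25771 of 34127 probes (75.5%) matched 1 symbol, giving 19740 symbols, and 8356 stayed unnamed but counted as genes under their accession, 27680 in all. Because the builds differ and no genome was used here, no coordinates are given. Another 42 probes were left out because all their spots on an array were marked.

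With 1 array per condition no test and no p-value was possible. Ratios were taken between 2 arrays for siRNA against control, wild type against control, each mutant against wild type, and L282P against H348Q, over genes with at least 50% of spots well above background on both arrays. A gene counted as higher or lower from a 2-fold ratio on, as a rule of size. For a gene above background on 1 of the 2 arrays, the bound set the bright value against the higher of the dim value and the lowest signal well above background on the dim array. The control, siRNA and wild-type arrays share a slide and the mutant arrays share another, so a slide term could not be fitted for mutants against wild type or control.

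Genes were grouped by 26 lists of 697 entries, of which 690 are on the array: NF-kB, immediate early and AP-1 subunit, JUN/AP-1, nuclear receptor, Wnt, Notch, MYC and p53 target genes, the NCoR/SMRT complex, interferon-stimulated, pan-B, germinal centre, plasma cell, antigen presentation, mitotic, DNA replication, apoptosis, ATF4 and unfolded protein response, heat shock and oxidative stress, cholesterol, glycolysis and hypoxia, oxidative phosphorylation and ribosomal protein genes, and markers of T and NK, myeloid, and epithelial and stromal cells. A list stood apart when its median log2 ratio lay outside the middle 95% of 10000 random lists of the same size matched on mean expression in 20 bins. This describes these arrays and is no test of the conditions. The groups, comparisons, lists, alternatives and the rule for named genes were set before the data were examined. That rule took per comparison the 10 genes with the largest ratio per direction among those at least 2-fold, not marked and brighter than the median gene, the 3 largest bounds per direction, the 10 most extreme genes common to both mutants, the highest and lowest 2 members of each list that stood apart with all members at least 2-fold where these were at most 4, and TBL1XR1 with its complex. Non-coding names without a symbol were counted, not named, and the text prints part of the genes the rule takes. Further list members printed as examples were picked from the fixed lists after their values were seen.

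Alternatives were normexp background correction (offset 50), quantile and cyclic loess normalization, genes above background on at least 1 of the 2 arrays, no filter on dim genes, the median over all probes of a gene, the authors' deposited ratio values, a 1.5-fold size, and for the mutants the control array or the mean of the first slide's 3 arrays as reference. The planned normexp used mean spot intensity, and since that column was not used here it ran on the median intensity and background. The procedure was tested on simulated data with 200 genes altered per comparison and a noise SD of 0.109 log2 per array: in the siRNA comparison (18171 genes) it called 96.0% of genes altered 2.5-fold, 100.0% of those altered 4-fold or 8-fold, 0.0% of those altered 1.5-fold and 0 unaltered genes, and 3 of 100 unshifted lists stood apart. In the other comparisons 2 to 6 of 100 such lists did. The noise was that of the closest pair of arrays, without outlier spots or culture variation. It is small beside a 2-fold ratio, so 0 unaltered calls were fixed in advance. The simulation checks the procedure and gives no error rate for these arrays. Values for comparisons that share an array were set beside 20 simulations of unchanged arrays. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.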

Results

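Gene expression was measured in BJAB, an established human B-lymphoma cell line, on 5 one-colour whole-genome oligonucleotide arrays. The series concerned TBL1XR1, a subunit of the NCoR/SMRT corepressor complex, and asked how 2 of its point mutations, L282P and H348Q, bear on corepressor, NF-kB and JUN target genes in lymphoma. Each of 5 conditions had 1 array: control cells, cells given a TBL1XR1 siRNA, and cells given a plasmid for wild-type, L282P or H348Q TBL1XR1 with a GFP tag. The labels do not say what the control cells received or when RNA was taken, and they give H348Q with glutamine in the titles and glutamic acid in the protocol text. There were no replicates of a condition, so no difference below was tested for significance, and words such as higher and lower describe these arrays. Each array had 43118 spots for genes, of which 66.4% (L282P) to 69.7% (siRNA) were well above background and 0 were saturated. The control, siRNA and wild-type arrays lay on the first slide and the L282P and H348Q arrays on the second, so a mutation and its slide cannot be told apart in any comparison with wild type or control.

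TBL1XR1 itself followed the labels on its brighter probe. Its signal was 2.96-fold lower on the siRNA array than on the control array (log2 ratio -1.57, SE from replicate spots 0.08), or 33.8% of control. On the plasmid arrays it was 4.99-fold higher with wild type (2.32), 2.98-fold higher with L282P (1.57) and 3.49-fold higher with H348Q (1.80). Against the wild-type plasmid, the same probe was 1.68-fold lower with L282P (-0.74) and 1.43-fold lower with H348Q (-0.51). A dimmer probe of the gene showed the knockdown, at -1.64 (SE 0.16), but not the plasmids, at -0.17 with wild type, 0.27 with L282P and 0.46 with H348Q against control. Against wild type it was 0.44 and 0.63 higher with L282P and H348Q, so the order of the plasmids rests on the probe. Where the 2 probes lie in the transcript was not used here, so whether the dimmer probe could see the plasmid insert is open.

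**Figure D1:**
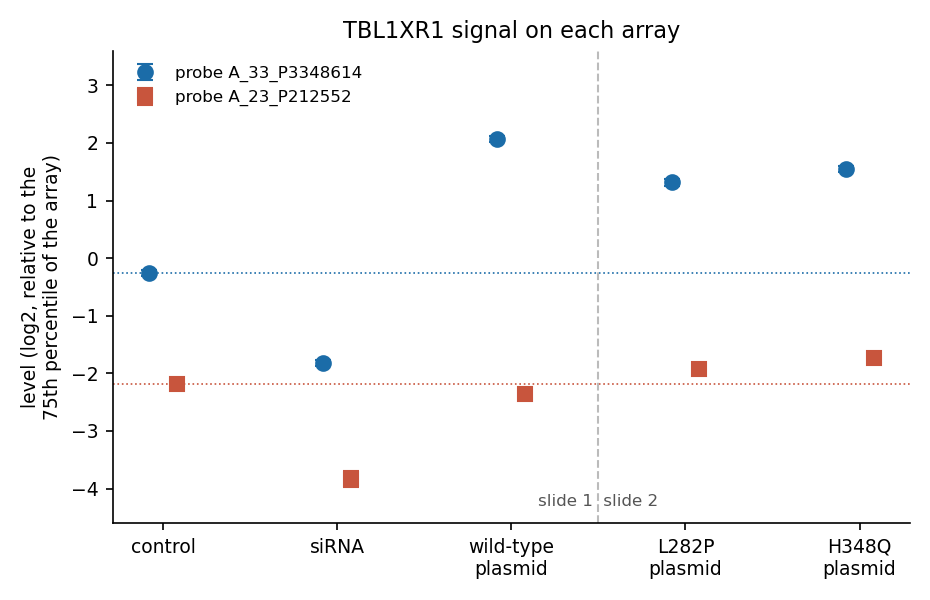
Level of TBL1XR1 on each of the 5 arrays (x axis, with the slides divided by a dashed line), as log2 signal relative to the 75th percentile of the array (y axis), for its 2 probes; bars are SEs from the spread of replicate spots and dotted lines mark the control array. Both probes were lower on the siRNA array (-1.57 and -1.64 from control), and the brighter probe was higher on the 3 plasmid arrays (1.57 to 2.32).

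The siRNA comparison asked which genes differ when TBL1XR1 is low. The control was not labelled as a non-targeting siRNA, so this comparison does not separate low TBL1XR1 from other effects of the siRNA. On the siRNA array, CHAC1, an enzyme that degrades glutathione, had the largest ratio, 44.2-fold higher (5.46, SE 0.07). CTH, which makes cysteine, was 9.42-fold higher, SESN2, a sensor of leucine, 8.68-fold higher, and SLC7A11, the cystine importer, 7.14-fold higher. The transcription factor ATF3 was 26.0-fold higher on its brightest probe, but only 0.01 and 1.47 higher in log2 on its other measured probes. The chemokine gene CXCL11 was 14.0-fold higher and CCL4, another, 6.17-fold higher. Some immediate early genes were among the lowest: EGR1 was 6.29-fold lower (-2.65), FOS 5.60-fold lower (-2.49) and DUSP2, a phosphatase of MAP kinases, 2.86-fold lower (-1.52). ID1, an inhibitor of helix-loop-helix factors, was 3.34-fold lower, the costimulatory gene CD86 2.16-fold lower and the heat shock gene HSPA1B 2.10-fold lower. In all, 202 genes were at least 2-fold higher and 72 at least 2-fold lower among 18171 genes well above background on both arrays. Genes with several probes differed between them by an SD of 0.199 log2. Of the 2-fold genes 73.7% were higher, and under the alternatives this share ran from 58.5% at 1.5-fold and 59.8% with no filter on dim genes to 88.0% with normexp background correction.

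Of the 26 gene lists, 14 lay outside the middle 95% of random lists of matched expression in the siRNA comparison. The 33 measured ATF4 and unfolded protein response genes had a median log2 ratio of 0.93, with 14 members at least 2-fold higher and 1, the chaperone HSPA5 (-1.02), at least 2-fold lower. Germinal centre B cell genes were higher (median 0.25, 16 of 19 above 0), among them CD38 (1.44), GCSAM and the repressor BCL6 (0.91). Plasma cell genes had a median of 0.17, above random lists, with CD38 and XBP1 at least 2-fold higher, but only 10 of 17 members were above 0. Higher as well were interferon-stimulated genes (0.17, 27 of 35 above 0, none 2-fold, IFIT2 0.66 on its brighter probe and 0.05 on the other), pan-B cell genes (0.10, CD22 0.66) and mitotic genes (0.11, 24 of 29 above 0). The p53 target genes had a median of 0.10 (14 of 25 above 0) with SESN2, CDKN1A (1.55, SE 0.43) and BBC3 (1.23) at least 2-fold higher, a call lost under 3 of 7 other settings, and with the median over all probes of a gene the list was at -0.03. CDKN1A rests on a single spot, and its control value (-6.82) lay close to the lowest signal well above background on that array (-7.00). All 38 ribosomal protein genes were slightly higher (median 0.13), a call lost under quantile and cyclic loess normalization.

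Lower on the siRNA array were NF-kB target genes (median -0.16, but -0.06 with normexp, and 21 of 27 below 0), with the cytokine genes EBI3 (-1.63) and TNF (-1.06) lower and the chemokine genes CCL4 (2.62) and CCL3 (1.43) higher. Immediate early and AP-1 subunit genes were lower (-0.25, 14 of 21 below 0), with EGR1, FOS, DUSP2 and KLF2 (-1.38) at least 2-fold lower and ATF3 and DUSP5 (1.76) at least 2-fold higher. The value of KLF2 on the siRNA array (-6.93) lay close to the lowest signal well above background on that array (-7.08). Genes of the MYC target list, which act largely in ribosome assembly, had a median of -0.16 (25 of 30 below 0, NOP16 -0.61, RRP9 -0.59). Heat shock and oxidative stress genes (-0.17, 19 of 25 below 0, HSPA1B -1.07, HSPA8 -0.92) and antigen presentation genes (-0.11, 18 of 25 below 0, CIITA -0.39) were lower as well. The 7 measured Notch target genes had a median of -0.23 (HEY1 -0.63), but this call was lost under 6 of 7 other settings.

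**Figure D2:**
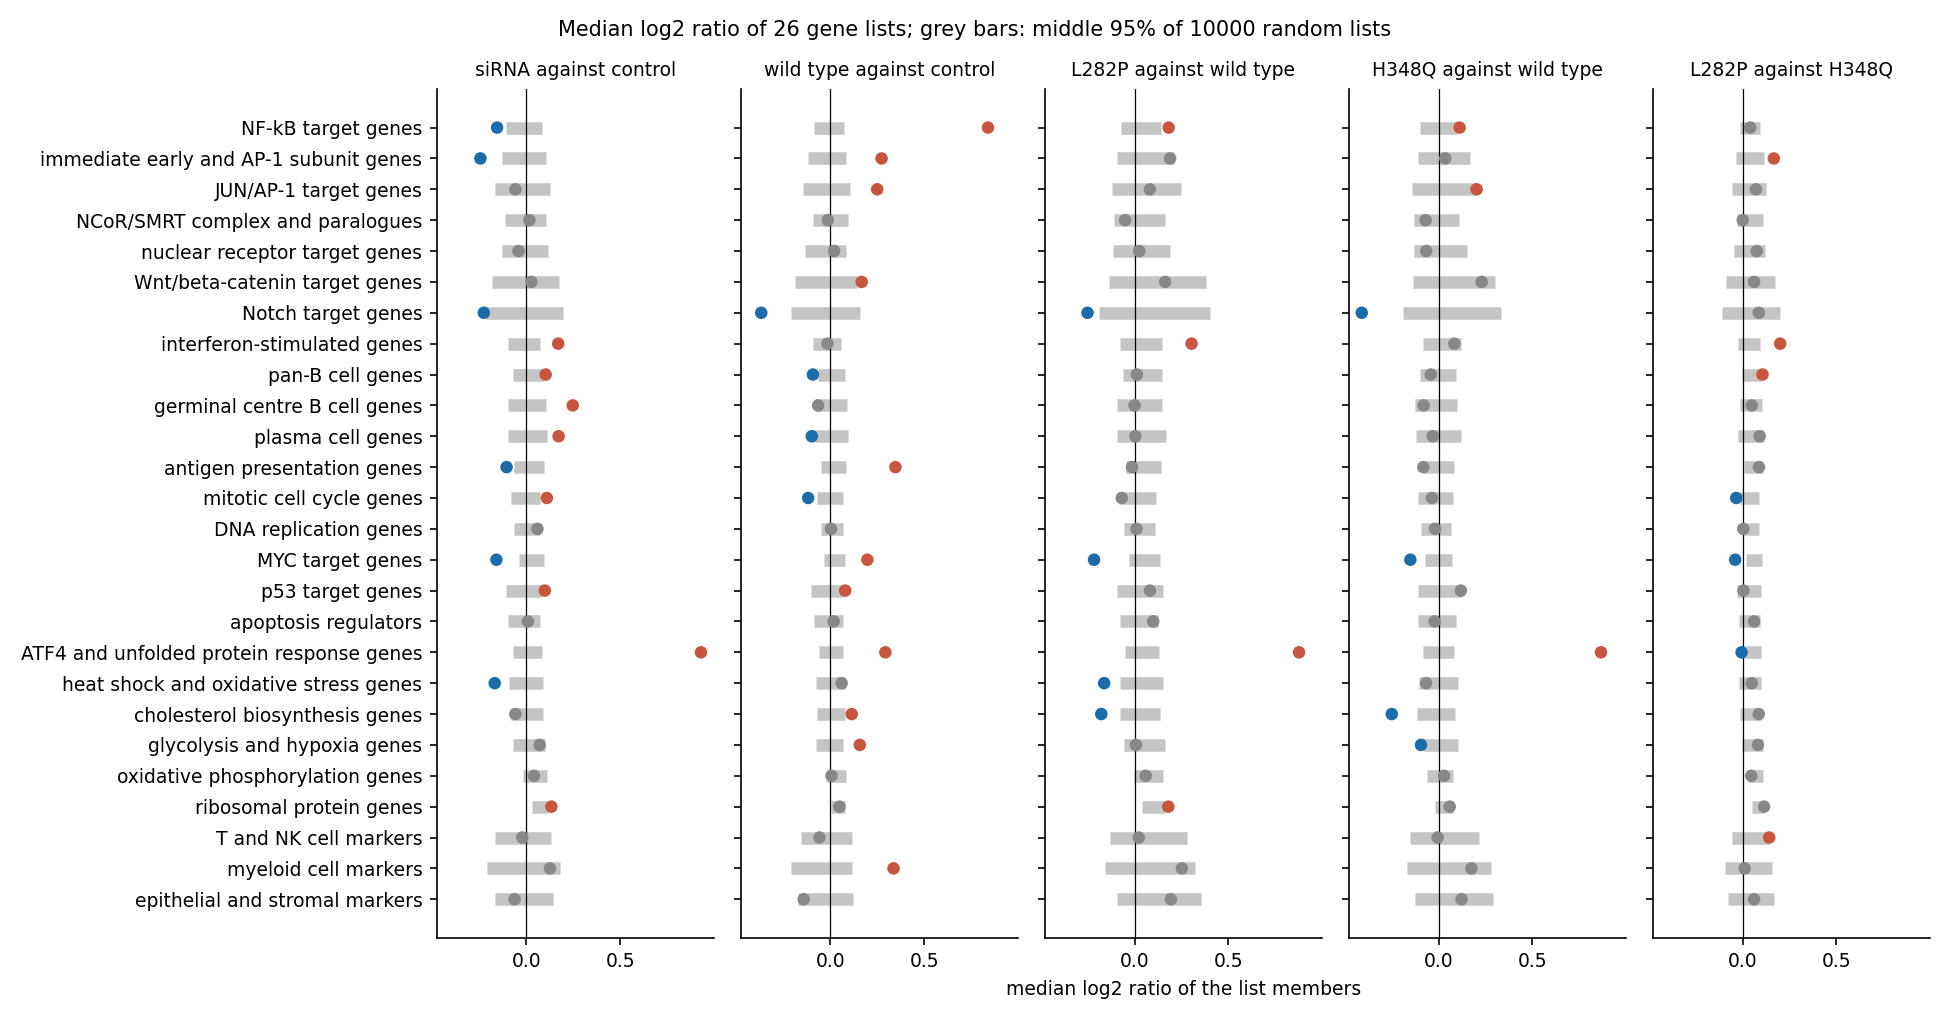
Median log2 ratio (x axis) of each of the 26 gene lists (y axis) in the 5 comparisons (panels), as points coloured where the list lay outside the middle 95% of 10000 random lists matched on expression (grey bars). ATF4 and unfolded protein response genes stood far right in the siRNA (0.93), L282P (0.88) and H348Q (0.87) panels, and NF-kB target genes in the wild-type panel (0.84).

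The wild-type plasmid was set against control to ask what added TBL1XR1 does. Members of the NF-kB target list were among the highest genes: EBI3, a cytokine subunit, was 21.7-fold higher (4.44, SE 0.05 from 10 spots per array), the chemokine gene CCL17 2.93 higher in log2, TRAF1, an adaptor of TNF receptors, 5.13-fold higher and the lymphotoxin gene LTA 2.16 higher in log2. Other large ratios were those of the potassium channel gene KCNN4 (11.2-fold higher), the gelatinase gene MMP9 (8.78-fold higher), IL4I1 (6.46-fold higher), the homing receptor gene CCR7 (5.68-fold higher) and MIR155HG, host of a microRNA (5.12-fold higher). CHAC1 was 12.8-fold higher here as well, and ATF3 6.11-fold higher on its brightest probe but by only 0.11 and 0.56 in log2 on others. Among the lowest genes were KBTBD11 (3.44-fold lower, -1.78), DNAJC22 (3.19-fold lower), TG (3.17-fold lower), the cell cycle inhibitor gene CDKN1C (2.83-fold lower), NAV2 (2.76-fold lower) and ID1 (2.55-fold lower). Altogether 151 genes were at least 2-fold higher and 128 at least 2-fold lower of 17941 measured, with an SD of 0.182 log2 between probes of a gene. The share that was higher, 54.1%, depended on the setting: it was 64.8% with normexp, but 48.5% and 49.4% with the wider filters on dim genes and 43.8% at 1.5-fold, so neither direction clearly had more genes.

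All 27 measured NF-kB target genes were above 0 on the wild-type array (median 0.84), 12 of them at least 2-fold, including CD83 (1.97), TNF (1.91), ICAM1 (1.77) and the NF-kB inhibitor gene TNFAIP3 (1.55). No array was labelled as an empty plasmid, so this comparison does not separate the encoded protein from plasmid DNA. Antigen presentation genes were higher in all 25 members (median 0.35), with the largest ratios in HLA-DQA1 (1.30), HLA-DMB (0.85) and the class II activator gene CIITA (0.76). Immediate early genes (0.27, 17 of 21 above 0, NR4A3 1.24, DUSP5 1.18), JUN/AP-1 target genes (0.25, but 0.11 with normexp, 11 of 15 above 0, MMP9 3.13, TIMP1 0.78) and all 30 MYC target genes (0.20, NOLC1 0.40, POLR1B 0.39) were higher. The ATF4 and unfolded protein response list was also higher, at 0.29 (24 of 32 above 0), with CHAC1, ATF3 and STC2 (1.14) at least 2-fold higher. Smaller medians above random lists were those of glycolysis and hypoxia genes (0.16, ADM 0.42), cholesterol synthesis genes (0.11, MSMO1 0.38) and p53 target genes (0.08, FAS 0.94). In the same order, these medians ran from 0.10 to 0.17, 0.09 to 0.13 and 0.07 to 0.14 over the settings. The p53 target CDKN1A was at 1.43 (SE 0.40), over a control value near background. Wnt target genes (0.17) stood apart too, but not under 3 of 7 other settings. Among markers of other cell types, the myeloid list was higher (0.34, but 0.13 with no filter on dim genes, and 9 of 11 above 0), with MS4A7 (1.73), CSF1R (1.40) and FCN1 (1.05) at least 2-fold higher and the monocyte marker CD14 at -0.27.

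Notch target genes were lower on the wild-type array (-0.37, 5 of 7 below 0, HEY1 -0.78). Over the settings their median ran from -0.37 to -0.10, and the call was lost with no filter on dim genes. Mitotic genes were lower by a small amount (-0.12, 22 of 29 below 0, BIRC5 -0.28). Pan-B cell genes had a median of -0.09, with VPREB3, a surrogate light chain gene, at -1.08 and MS4A1, which encodes the antigen CD20, at 1.14. Plasma cell genes had a median of -0.10, with CD27 at -1.10 and SLAMF7 at 0.90. The pan-B call was lost with 2 of 7 other settings and the plasma cell call with the median over all probes.

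Each mutant was compared with the wild-type plasmid to ask what the mutation alters. Among the highest genes in both comparisons was the chemokine gene CXCL10, 15.1-fold higher with L282P and 17.7-fold higher with H348Q (SE of the log2 ratios 0.28). CTH was 9.70-fold higher with L282P (3.28, SE 0.08) and 11.2-fold higher with H348Q (3.48), SLC7A11 9.32-fold and 11.7-fold higher, SESN2 5.70-fold and 6.29-fold higher, and the chemokine gene CXCL11 6.98-fold and 9.44-fold higher. The receptor gene VLDLR was 6.31-fold and 6.88-fold higher on its brighter probe, but only 1.12 and 1.08 higher in log2 on its other probe. The glycine transporter gene SLC6A9 was 5.09-fold higher with L282P, and CBS, which acts before CTH in cysteine synthesis, 5.82-fold higher with H348Q. The matrix gene MFAP4 was 5.17-fold and 6.29-fold higher. ATF3 was 7.75-fold and 8.27-fold higher, while its 3 other probes lay between 0.39 and 2.63 with L282P and between 0.29 and 2.78 with H348Q. Chaperone genes of the heat shock and ATF4 lists were among the lowest: HSPA8, the constitutive cytosolic chaperone, was 2.70-fold and 2.78-fold lower (-1.44 and -1.47), HSPA5, the chaperone of the endoplasmic reticulum, 2.38-fold and 3.01-fold lower, HSPA1B 2.26-fold and 3.03-fold lower and SDF2L1 2.06-fold and 2.24-fold lower. DNAJB1 (2.09-fold lower), ID1 (2.29-fold lower) and TNFRSF12A (2.07-fold lower) were at least 2-fold lower with H348Q. MSANTD2 was 262.9-fold higher with H348Q, on a single spot with no second probe.

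Against wild type, L282P had 460 genes at least 2-fold higher and 60 at least 2-fold lower of 17543 measured, and H348Q had 466 in either direction, 118 of them lower, of 17980, with SDs of 0.240 and 0.239 log2 between probes of a gene. The share of these genes that was higher depended on the setting. With L282P it was 88.5%, against 95.7% under normexp, 72.6% under quantile and 78.4% under cyclic loess normalization and 66.7% when genes above background on at least 1 array were kept, and with H348Q it was 74.7%, against 90.7% under normexp, 56.6% under quantile and 63.0% under cyclic loess.

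The ATF4 and unfolded protein response list had medians of 0.88 with L282P (13 of 32 members at least 2-fold higher, 2 lower) and 0.87 with H348Q (13 higher, 3 lower), and the lower members were the endoplasmic reticulum genes HSPA5 and SDF2L1, joined by MANF (-1.04) with H348Q. Its high members included PSAT1 (1.94 and 1.98), a serine synthesis enzyme, the factor gene CEBPB (1.65 and 1.62) and ASNS, asparagine synthetase (1.41 and 1.52). NF-kB target genes had small medians, 0.18 with L282P and 0.11 with H348Q, each with 17 of 29 above 0. CXCL10, CCL4 (2.24 and 2.40) and CCL3 (2.14 and 2.10) were at least 2-fold higher, and TNF (-0.71 and -0.87) and LTA (-0.39 and -0.50) lay below 0. The first of these calls was lost under quantile normalization and the second without a filter on dim genes.

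MYC target genes were lower with both mutants than with wild type (-0.22 and -0.15), most of all TFRC, the transferrin receptor gene (-0.91 and -0.87). Against control the MYC target list was inside the random range with both mutants (-0.01 and 0.03), while wild type stood 0.20 above control. Cholesterol synthesis genes (-0.18 and -0.25, MSMO1 -0.69 and -0.59) were also lower than with wild type. So were Notch target genes (-0.25 and -0.41, but -0.17 and -0.26 with no filter on dim genes, HEY1 -0.40 and -0.84). Heat shock and oxidative stress genes were lower with L282P (-0.16, but -0.07 with no filter on dim genes, 16 of 25 below 0) and inside the random range with H348Q (-0.07), although HSPA1B, HSPA8 and DNAJB1 were at least 2-fold lower there. Interferon-stimulated genes were higher with L282P (0.30, 32 of 35 above 0, OASL 0.79) and inside the random range with H348Q (0.08). The ribosomal protein list stood at 0.18 with L282P, but at -0.00066 under quantile and 0.09 under cyclic loess normalization, where its call was lost. JUN/AP-1 target genes stood at 0.20 with H348Q, with HBEGF, a growth factor gene, at 1.24 and CCND1, cyclin D, at -0.82, a call lost under 5 of 7 other settings, and at 0.08 with L282P, inside the random range, as they were on the siRNA array (-0.06). Glycolysis and hypoxia genes stood at -0.09 with H348Q, with PFKL at 1.54, a call lost under 4 of 7.

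**Figure D3:**
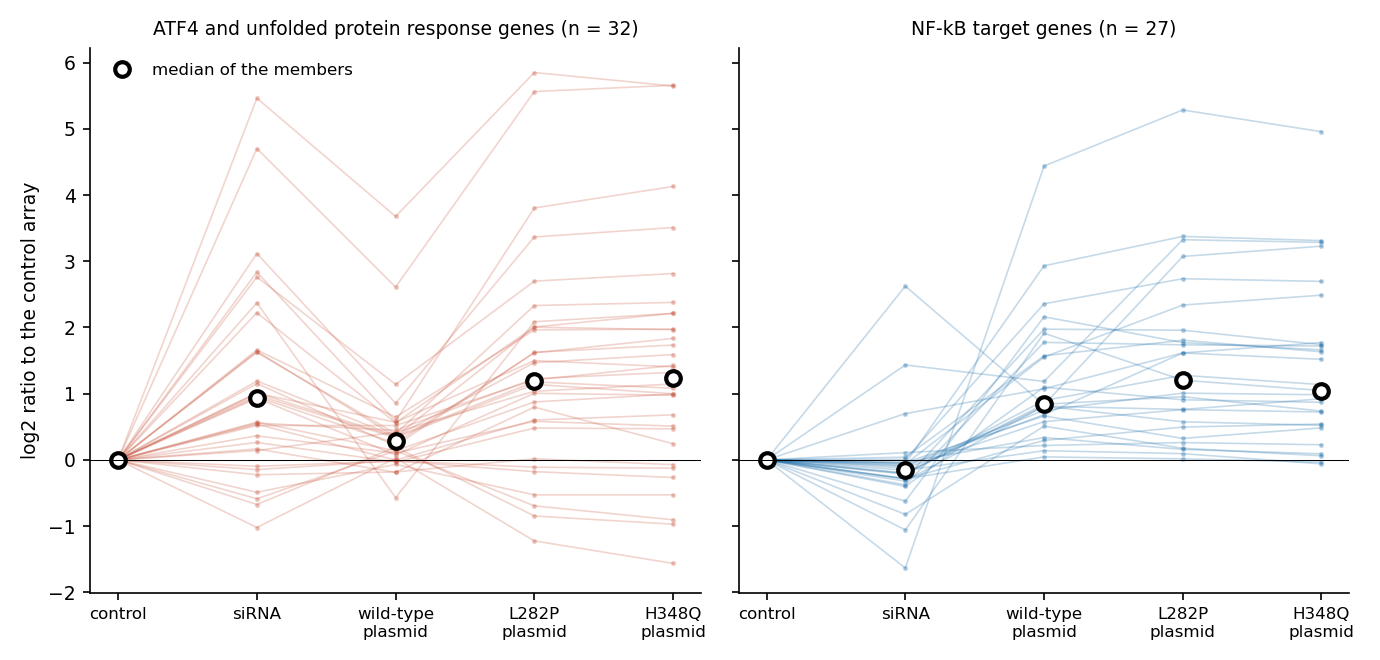
Log2 ratio to the control array (y axis) of each member measured on all 5 arrays (x axis) for the ATF4 and unfolded protein response list (n = 32, left) and the NF-kB target list (n = 27, right); thin lines are genes and open circles medians. The ATF4 medians were 0.94 on the siRNA, 0.29 on the wild-type, 1.19 on the L282P and 1.23 on the H348Q array, and the NF-kB medians -0.16, 0.84, 1.20 and 1.05.

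Set against both the wild-type and the control array, both mutants gave 183 genes at least 2-fold higher in all 4 comparisons and 17 at least 2-fold lower, of 17361 measured on these 4 arrays. Of these, 53 and 4 could be named under the rule, which takes genes with a symbol that are brighter than the median gene. Among the nameable genes the highest by their smallest ratio were CTH (at least 3.28 in each comparison), SLC7A11 (3.22), ATF3 (2.95), CXCL11 (2.80), SESN2 (2.51), MFAP4 (2.37), CCL4 (2.24), FAM177B (2.21), GPT2, an alanine aminotransferase (2.16), and CBS (2.16). Lowest among them were HSPA8 (-1.32 or lower in each), HSPA5 (-1.22), HSPA1B (-1.16) and the transcription factor gene FOXI1 (-1.02). Across 17500 genes the L282P and H348Q ratios to wild type had a Pearson r of 0.84 and a Spearman rho of 0.83, where the shared wild-type array alone gave a simulated r of 0.50 for unchanged genes. The covariance was 0.129 against a simulated 0.0119. The simulated arrays hold only independent noise the size of that between the mutant arrays, without slide or culture variation. The excess over them therefore does not separate agreement of the mutations from the shared slide or the shared wild-type culture. Of genes at least 2-fold higher, 250 were common to both (8.68 expected if independent), and of those lower 36 (0.305 expected), an excess to which the shared array may add. With no array in common, L282P against wild type and H348Q against control had r 0.63, and the opposite pairing r 0.67, although both mutants still shared a slide. The first of these was 0.563 with genes above background on at least 1 array kept and 0.340 with no filter on dim genes.

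The mutants were closest to each other. L282P against H348Q, arrays of the same slide, had 73 genes at least 2-fold higher and 42 at least 2-fold lower of 17830, and 95% of log2 ratios lay between -0.36 and 0.50. Few well-expressed genes passed 2-fold: RNA5-8SN5, a ribosomal RNA gene (2.43-fold higher with L282P), SLC6A12, a betaine transporter gene (2.22-fold higher), GALNT9-AS1 (2.41-fold lower) and the single-spot MSANTD2 (309.6-fold lower). TBL1XR1 was at -0.23 between the mutants. Interferon-stimulated genes were higher with L282P (median 0.20, 30 of 35 above 0), among them RSAD2 (0.71, SE 0.28), IFIT1 (0.69) and MX1 (0.59). Immediate early genes were higher too (0.17, 19 of 22 above 0, KLF2 0.54, EGR4 0.39). MYC target genes (-0.04), mitotic genes (-0.03) and the ATF4 list (-0.01, and 0.00091 with the median over all probes) lay just below random lists, whose medians were above 0. Under other settings they reached -0.09, -0.07 and -0.07 at the lowest. Pan-B cell genes (0.11, CD79B 0.28) and T and NK cell markers (0.14) stood apart above, but lost that call under 3 and 4 of 7 other settings. Of the 2-fold genes 63.5% were higher, but with genes above background on at least 1 array kept it was 38.7% (270 higher and 428 lower), and normexp left only 3 higher and 4 lower.

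The siRNA comparison and the mutant comparisons shared many of their highest genes although they have no array in common. Of genes at least 2-fold higher on the siRNA array, 86 were also at least 2-fold higher with L282P against wild type (4.35 expected if independent) and 87 with H348Q (3.34 expected). Among them were CTH (3.24 on the siRNA array), SLC7A11, SESN2, MFAP4 (2.44), GPT2 (2.24) and CBS (1.75). Of lower genes, 7 and 9 were shared (0.191 and 0.395 expected), HSPA5 and HSPA1B among them. Across genes, which are not independent replicates, r was 0.51 with L282P (17348 genes) and 0.48 with H348Q (17662 genes). Simulated unchanged arrays gave -0.00053 and 0.00055. Their noise is independent and no array is shared, so values near 0 were fixed in advance and are no support for the correlation.

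**Figure D4:**
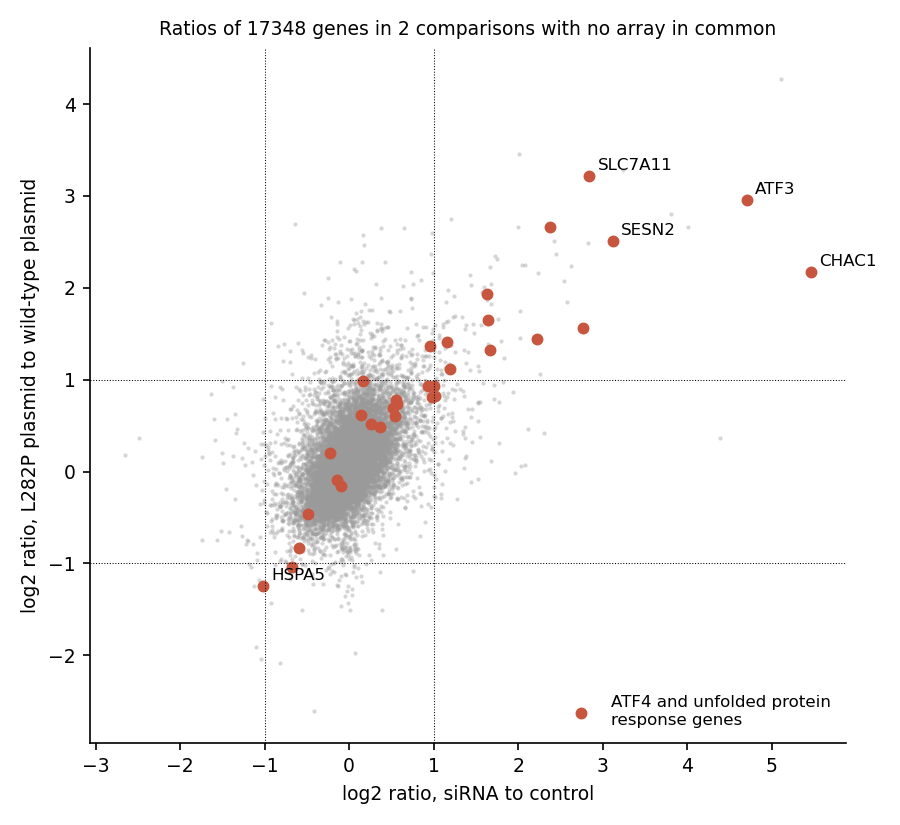
Log2 ratio of each of 17348 genes for siRNA against control (x axis) and L282P against wild type (y axis), with ATF4 and unfolded protein response genes in red and dotted lines at 2-fold. CHAC1 (5.46 and 2.17), ATF3 (4.70 and 2.95), SESN2 (3.12 and 2.51) and SLC7A11 (2.84 and 3.22) lie at the upper right and HSPA5 (-1.02 and -1.25) at the lower left.

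The NCoR/SMRT complex, to which TBL1XR1 belongs, stayed inside the random range in every comparison, with medians of 0.02 (siRNA), -0.01 (wild type), -0.05 (L282P), -0.07 (H348Q) and 0.00 between the mutants over 17 members. Besides TBL1XR1 itself, BCL6 had the largest ratio among the members on the siRNA array (0.91), next to the paralogue TBL1X, which was 0.89 higher in log2 on the siRNA array and 0.78 and 0.72 higher with L282P and H348Q against wild type, but 0.16 with wild type against control. NCOR1 (-0.10), HDAC3 (0.02) and GPS2 (0.03) showed small ratios on the siRNA array, and BCORL1 was at -0.32 and -0.58 with the mutants. Nuclear receptor target genes were inside the random range as well (-0.04, 0.02, 0.03, -0.07 and 0.08 in the same order), although the glucocorticoid target TSC22D3 was at 1.55, 1.59 and 1.49 in the siRNA, L282P and H348Q comparisons. Apoptosis regulators (0.01, 0.02, 0.10, -0.02 and 0.06) hid single members such as BCL2 (1.34 with wild type against control, 1.27 and 1.48 with the mutants against wild type) and PMAIP1 (1.58 on the siRNA array). DNA replication genes (0.06, 0.00, 0.01, -0.02 and 0.00) and oxidative phosphorylation genes (0.04, 0.01, 0.06, 0.03 and 0.05) were inside the range, as were epithelial and stromal markers (-0.06, -0.14, 0.19, 0.12 and 0.06), where COL1A1 was at 2.96 and PECAM1 at -1.96 on the wild-type array. Single members in these lists were picked after their values were seen. Of 130 list comparisons, 51 stood apart, and 37 of them did so under all 7 other settings. Among these settings, the authors' deposited ratios hold the same log2 differences up to a constant per pair, so they add little as a check. With independent genes and comparisons 6.5 would be expected to stand apart. Members of a list may vary together, lists share members and comparisons share arrays, so the excess over 6.5 does not measure an effect of the conditions.

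Some genes were above background on only part of the arrays, which gives a bound. The only probe of FLT1 was at least 7.72-fold brighter on the siRNA array than on the control array, and that of JUN, whose product is an AP-1 subunit, at least 8.60-fold brighter on the wild-type array. Each was above background on that array alone, as are the probes that are bright on a single array described at the end, so neither bound is read here as a difference between conditions. OR1E1 was at least 18.4-fold lower with wild type than with control and was above background on the other 4 arrays. It has no other probe, so its bound rests on the dim value of the wild-type array alone. GDAP1L1 was at least 14.4-fold higher with L282P and 20.2-fold higher with H348Q than with wild type, and DRD5 at least 11.1-fold and 15.4-fold higher. Each of these was above background on 3 arrays, so not on the mutant arrays alone. None of these bounds is read here as a difference between conditions either.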

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

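All alternatives here were set before the data were examined, and none was added afterwards. No paired analysis was possible because each group had 1 array, and the slide block could not be fitted because the mutant arrays are alone on their slide. With the mean of the first slide's arrays as reference instead, the mutants' counts stayed within 1.5 times of those against wild type, as did most counts under quantile and cyclic loess normalization and all counts under the authors' deposited ratios. For the deposited ratios this was largely fixed in advance, since they hold the same log2 differences between arrays up to a constant per pair. The knockdown of TBL1XR1 lay between -1.46 and -1.60 under every alternative that gives it. Counts of genes at least 2-fold higher and lower are given in the order siRNA, wild type against control, L282P, H348Q against wild type, and L282P against H348Q. Normexp, whose offset pulls ratios of dim genes toward 0 by construction, gave 95, 68, 132, 127 and 3 higher and 13, 37, 6, 13 and 4 lower. Keeping genes above background on at least 1 array, which adds dim genes by construction, gave 574, 422, 897, 988 and 270 higher and 291, 449, 447, 433 and 428 lower, and no filter gave 1047, 878, 1838, 1678 and 791 higher and 704, 900, 744, 825 and 712 lower. A 1.5-fold size gave 658, 457, 1697, 1292 and 309 higher and 467, 587, 374, 544 and 151 lower. Quantile normalization gave 124 lower genes with L282P and 198 with H348Q, and cyclic loess 99 with L282P, and the cause was not tested. With the control array as reference, L282P had 747 higher and 169 lower and H348Q 608 and 318. The median over all probes gave 65 lower genes for L282P against H348Q (the cause was not tested), and put TBL1XR1 with the wild-type plasmid at 1.07 above control instead of 2.32, since it averages a probe that shows the plasmid with one that does not. The correlation of L282P against wild type with H348Q against control, 0.63, was 0.563 and 0.340 with the wider filters, which add genes near background. List medians that changed sign were p53 target genes on the siRNA array (-0.0299) and the ATF4 list between the mutants (0.00091), both with the median over all probes, and ribosomal protein genes with L282P under quantile normalization (-0.00066), and the cause was not tested. Of other list medians 124 moved by more than the spread of random lists and 790 did not, and of single-gene ratios 82 moved and 1653 did not. Signal over background limits the dim genes: 66.4% to 69.7% of spots were well above background.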

Other observations

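The tests on ATF4 and NF-kB target genes were chosen after their results were seen, while those on probes bright on a single array were written before. Some genes of small structural RNAs, picked because their values were high, were higher on the siRNA array than on the control array, and all such genes as a class were not tallied. RNA5-8SN5 was at 7.03 against 2.64 (log2 relative to the array's 75th percentile), the spliceosomal RNA gene RNVU1-18 at 5.76 against 3.46, RNU12 at -2.68 against -4.93, the Cajal body RNA gene SCARNA10 at -2.56 against -4.67 and RMRP, an RNA of an endoribonuclease, at 1.28 against -0.10. The long ribosomal RNA genes RNA18SN5 (2.34 against 2.32) and RNA28SN5 (8.50 against 8.45) were close to control. The probe of RNA5-8SN5 was at 2.17 with wild type, 2.54 with L282P and 1.26 with H348Q.

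Within the ATF4 and unfolded protein response list, 16 genes of the amino acid response and 9 genes of folding in the endoplasmic reticulum, were grouped after the values were seen, so their medians describe the list and test nothing. All 16 were above 0 in the siRNA comparison (median 1.41) and in L282P (1.43) and H348Q (1.60) against wild type, and 10 of them were at least 2-fold higher in all 3. The folding genes had medians of -0.22, -0.16 and -0.25 but went both ways, with 2, 3 and 3 of 9 above 0 and MANF at -0.59, -0.83 and -1.04. Against the siRNA array, NF-kB target genes were higher with L282P (1.24) and H348Q (1.20).

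ATF4 target genes were high on the siRNA, L282P and H348Q arrays and less so on the wild-type array. The slide as the cause is argued against for the siRNA part, because siRNA and control share a slide and their median was 0.93, above all 10000 random lists. Unfolded protein in the endoplasmic reticulum stays open: the highest of the 3 medians of its chaperone genes was -0.16, but these 9 genes were chosen afterwards and went both ways, and XBP1 of the same response was at 4.28 on the siRNA, 4.78 on the L282P and 4.68 on the H348Q array against 3.28 on control and 3.85 with wild type. For the mutants the slide cannot be told apart from the mutation, as the list lay up to 0.25 above the siRNA array across slides. A culture state such as used-up amino acids stays open as well. The lowest median of the amino acid genes was 1.41, but these genes were grouped after the values were seen, so it is no support. Reduced TBL1XR1 function, as a hypothesis, also predicts high values, with no replicate culture to separate the 2 explanations. The list was above control on every array given siRNA or plasmid. It was 0.29 higher with the wild-type plasmid, which reduced function alone does not predict. What transfection itself adds was not tested.

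NF-kB target genes were high on all 3 plasmid arrays. The slide is argued against for the wild-type part, as wild type and control share a slide and the median was 0.84, above all 10000 random lists, while for the mutants, 0.11 or more above wild type across slides, slide and mutation cannot be told apart. Electroporation stays open: the siRNA array, also electroporated, had the list at -0.16 (-0.06 with normexp), but it is 1 array and carries the knockdown too. Plasmid DNA, whatever it encodes, could likewise be the cause, since the lowest mutant median against control was 1.05 and no array was labelled as an empty plasmid. That more TBL1XR1 protein raises these genes is therefore a hypothesis that stays untested.

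Single probes, 210 in all, were at least 8-fold brighter on 1 array than the median of the 5 and at background on the other 4, from 25 on the control to 55 on the H348Q array. Artefacts of single spots are a possible source. Of 61 such genes with another probe, 3 (4.92%) had it at least 2-fold brighter on that array, where under 20% was set for this explanation in advance. All 3 were among 19 on the H348Q array. Another probe too dim to detect the gene also lowers this share. How many of the other probes were measurable is not given here, so the share cannot decide the question. For the condition of an array as the cause, over 3 times the count of each other array was set in advance. The highest count was 2.2 times the lowest, which argues against 1 condition giving most of these probes. It cannot exclude a smaller effect. The L282P (53) and H348Q (55) arrays, alone on the second slide, had the highest counts. A smaller effect of slide or condition stays open, as do the 3 genes of the H348Q array. MSANTD2, 262.9-fold higher on the H348Q array than on the wild-type array, has no second probe to check it, nor have FLT1 on the siRNA and JUN on the wild-type array.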
